A study of Homo sapiens with 6 samples.

How the data were processed

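Poly(A) RNA of OVCA433 cells was made into strand-specific libraries by the dUTP method with about 15 cycles of PCR, per the labels' protocols. The deposited table holds whole-number counts per gene for 6 libraries, with an Ensembl gene ID and a symbol per row. Per the submitters' processing notes, CASAVA and StringTie were used; their versions, the aligner, the genome build and the annotation are not given in the sources used here, nor is whether the counting used strand. Reads that fit near-identical copies or overlapping genes may therefore have been split, and genomic positions are given only from the reference annotation, GENCODE 29 on GRCh38. The sequence of the reagent behind the si group is likewise not given in the sources used here. PCR copies were not told apart by molecular identifiers, so counts are not independent molecules. In the table, 773 rows had a placeholder in place of a symbol and 10 had a symbol turned into a date; these took the symbol of the same gene ID in a reference name table, which matched 26567 of 26699 IDs. List genes whose symbols found no row were not analysed here.

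Columns were assigned to samples by name, and groups and replicate numbers were taken from the labels. Total counts were 40601423, 44130601 and 38031056 in sinc replicates 1, 2 and 3, and 35936577, 40144134 and 33778707 in si replicates 1, 2 and 3. Library pairs within a group differed by far more than sampling noise (chi-square per gene between 14.0 and 61.1), so that none was taken for a repeat of another. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr at a minimum count of 10, scaled by TMM, and tested with glmQLFit and glmQLFTest with the group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of the F statistic. CPM, counts scaled to the library size, used the TMM factors. The common biological coefficient of variation was 18.8%.

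Gene lists, 37 in number, were fixed before the data were examined, and 34 had at least 5 measured members. They were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, adjusted over the 34 lists. None of the 5 calls held with a correlation estimated for each list. Named genes were also chosen by a rule fixed beforehand: SOGA1, MTCL1 and SOGA3; the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 5 CPM, no overlap between the groups and an approved-style symbol; the 5 smallest adjusted p in each direction under the same conditions; and per list up to 4 members past the threshold with the smallest adjusted p, or the 2 most abundant where none passed. Some genes that this rule takes are not reported here.

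The alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no filter, a minimum count of 50, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Chosen after the data were seen were a correction of each library for transcript length and GC content (splines with 4 degrees of freedom, entered as offsets), the same genes without it, and counts without genes that share sequence with SOGA1. Length, GC content, coding sequence and UTRs came from 1 coding transcript per gene in GENCODE 29, the one with the longest coding sequence, which 12829 of the genes tested had (82.4%).

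Shared sequence was searched for after the results were seen. The log2 fold changes were regressed on the length and GC content of the transcript and of its 3' UTR, on abundance, and on the squares of these. The mean residual of genes with and without each short sequence was compared, and sequences were ranked by z, the difference over its standard error. There were 14 scans: 6-, 7- and 8-base sequences in 3' UTRs and in coding sequence, and 9-, 10-, 11- and 12-base sequences of SOGA1 on both strands. An earlier round with other covariates and statistics had picked out the same 7- and 12-base sequences. The lowest 7-base sequence in 3' UTRs and the lowest 12-base sequence of SOGA1 were each also picked on a random part of the genes and measured on the rest. The 21-base stretch and the minimum run of 11 bases were also set after the results were seen.

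On simulated counts for si against sinc, drawn for 15562 genes in 5 draws with 200 changed genes each, the edgeR test recovered 17.4% of genes changed by 0.5 on the log2 scale, 57.8% of those changed by 1 and 91.6% of those changed by 2. Of its 592 calls 8.78% were false, above the nominal 5%; the number of draws was raised to 5 after a first single draw had also lain above it. A list planted at -0.5 was called by camera and no other was. These genes were drawn independently of each other and without a length trend. The draw therefore cannot show how often camera calls unchanged lists in real libraries, where genes move together. In a simulated length trend with no changed gene, the correction took the calls from 2097 to 0 of 12702 genes. The search for short sequences found a planted 7-base sequence in 3 of 3 draws over 12497 genes.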

Results

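Gene expression was measured by RNA sequencing in OVCA433, an established human ovarian cancer cell line, in 3 libraries of a group named sinc and 3 of a group named si. The labels do not spell out either name. The series title states that the study asks how a deficiency of SOGA1, a coiled-coil protein gene on chromosome 20, changes expression in ovarian cancer cells. The deposited table held counts for 26699 genes. Total counts per library ranged from 33778707 in si replicate 3 to 44130601 in sinc replicate 2. No label says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Unless another test is named, adjusted p-values are from edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over the 15562 genes tested, and changes are si minus sinc.

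SOGA1 (ENSG00000149639; chromosome 20, 36777442 to 36863686, minus strand, in GENCODE 29 on GRCh38) was lower in all 3 si libraries. Its level was 64.4, 59.7 and 63.9 CPM (counts scaled to the library size) in sinc replicates 1, 2 and 3, and 25.3, 27.2 and 20.2 CPM in si replicates 1, 2 and 3. The means were 62.7 ± 2.60 CPM in sinc and 24.3 ± 3.64 CPM in si (SD, n = 3 each), so that si held 38.7% of the sinc level. The log2 fold change was -1.37 (SE 0.11, adjusted p = 0.000963). An exact two-sided permutation test of the 6 CPM values gave p = 0.1, the smallest that 3 against 3 allows. MTCL1, a paralog of SOGA1 that encodes a microtubule-crosslinking protein, was also lower, at 18.8 ± 1.70 CPM in si against 30.6 ± 1.49 CPM in sinc (SD, n = 3 each; log2 fold change -0.70, SE 0.10, adjusted p = 0.0079). The call on MTCL1 ended when sinc replicate 1 was left out. The paralog SOGA3 stood at 1.94 ± 0.677 CPM in si and 3.10 ± 1.52 CPM in sinc (SD, n = 3 each), a difference that did not pass the test (adjusted p = 0.30). The transcripts of MTCL1 and SOGA3 each share a run of 11 bases with GAAGGAGGAGCTGCTGAAGTA, a 21-base stretch of the SOGA1 coding sequence in exon 5 of 15 (chromosome 20, 36816186 to 36816206) that was picked after the data were seen. The 3' UTR of SOGA3 also holds 2 copies of TGAAGTA, the end of that stretch. The MTCL1 transcript used had no annotated 3' UTR, so it could not be searched there.

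**Figure D1:**
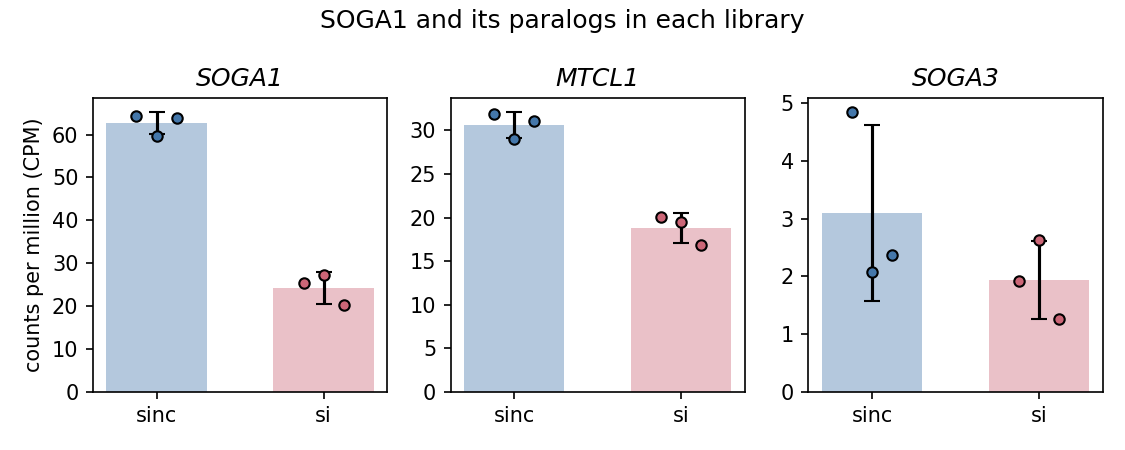
Level of SOGA1, MTCL1 and SOGA3 in CPM (vertical axis) in the sinc and si groups. Points are the 3 libraries of each group, bars their mean and error bars the SD; the SOGA1 values of si, between 20.2 and 27.2, all lie below those of sinc, between 59.7 and 64.4.

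Across the transcriptome, 1579 genes differed between the groups, 645 higher and 934 lower in si. Large changes were mostly decreases. Of 137 genes that changed at least 2-fold, 15 were higher and 122 were lower. The median change over all genes tested was 0.0058 on the log2 scale. The groups' CPM values did not overlap for 5425 genes, which is 34.9% of those tested. A single gene would do so in 10% of random groupings. Genes are not independent, so the share over all genes can lie far from 10% without a group effect. It was not computed for other splits. With upper-quartile scaling the split was 1005 higher and 890 lower. The count depended on single libraries: it was 203, 480 and 306 without sinc replicate 1, 2 or 3, 357 without si replicate 1 and 2563 without si replicate 2. The count at 2-fold was 71 without sinc replicate 1, 89 without sinc replicate 3 and 613 without si replicate 2. Correction of each library for transcript length and GC content, chosen after the data were seen, left 585 of 12829 genes, against 1786 on the same genes without it.

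Among genes that met the naming rule, the largest decreases fell on genes of several unrelated functions. ENO1, which encodes the glycolytic enzyme enolase, went from 4392 ± 195 CPM in sinc to 622 ± 201 CPM in si (SD, n = 3 each; log2 fold change -2.82, SE 0.23, adjusted p = 0.000935). PACSIN3, an endocytosis adaptor, fell by 2.18 on the log2 scale, and SUPT16H, a subunit of the histone chaperone FACT, fell by 2.13. CYFIP1, a component of the WAVE actin-regulatory complex, shared the smallest adjusted p with EIF2S2 (log2 fold change -2.08, SE 0.08, adjusted p = 6.41e-05; 218 ± 6.79 CPM in sinc and 51.5 ± 4.32 CPM in si, SD, n = 3 each). SLC26A2, a sulfate transporter, IQGAP1, a scaffold protein of the actin cytoskeleton, and IWS1, a transcription elongation factor, had log2 fold changes of -2.05, -2.04 and -2.01. EIF2S2, which encodes the beta subunit of the translation initiation factor eIF2, fell by 1.93 (SE 0.08). Its value is uncertain because a pseudogene copy, EIF2S2P4, named after its value was seen, was counted beside it at -1.79. EIF3C and EIF3CL, near-identical copies for a subunit of initiation factor eIF3, stood at -1.96 and -1.97, and the counting may have split their reads. MCMBP, which binds the MCM helicase complex, fell by 1.54, and MTOR, the kinase of the mTOR complexes, fell by 1.20 (SE 0.06, adjusted p = 0.000129). All of these but EIF2S2P4, which was not followed, passed the threshold in each of the 6 fits that left out 1 library. The largest fitted decrease among the named genes, SENP3-EIF4A1 at -7.75 (SE 2.00, adjusted p = 0.0492), belongs to a read-through locus that overlaps EIF4A1. Its sinc level was 101 ± 163 CPM (SD, n = 3), and it did not pass in any of the 6 fits with a library left out.

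Of the genes tested that have a coding transcript, SOGA1 aside, 8.96% share a run of at least 11 bases with the 21-base SOGA1 stretch and 11.4% hold its last 7 bases, TGAAGTA, in the 3' UTR. A run of 11 bases by itself went with little change. The 728 genes with that longest run had a median log2 fold change of -0.021, against -0.034 for the 1781 with 10. ENO1 and MTOR carry a run of 13 bases in their coding sequence that is identical to part of that stretch, EIF2S2 and IQGAP1 carry 14, SUPT16H 15, and PACSIN3, CYFIP1 and IWS1 carry 16. The longest such run in EIF3C and EIF3CL was 10 bases and in SENP3-EIF4A1 it was 8. SLC26A2 and MCMBP have runs of 8 and 9 bases, and each holds TGAAGTA once in its 3' UTR.

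The increases that met the naming rule were smaller. A gene with a clone name, AL157935.2, named after its value was seen, stood at 2.59 with 36.2 CPM in si. OGFR, the opioid growth factor receptor, rose from 88.6 ± 14.5 CPM in sinc to 214 ± 17.4 CPM in si (SD, n = 3 each; log2 fold change 1.27, SE 0.12, adjusted p = 0.0018). EMC6, a subunit of the endoplasmic reticulum membrane complex, rose by 1.08 and had the smallest adjusted p of the increases (0.000807). CHST14, a dermatan sulfotransferase, rose by 1.03, the syntaxin gene STX12 by 1.01 and the zinc finger gene ZCCHC3 by 0.98. GANAB, the catalytic subunit of glucosidase II in the endoplasmic reticulum, rose by 0.94, from 410 ± 52.0 to 788 ± 40.3 CPM (SD, n = 3 each). MED11, a Mediator subunit, RGS19, a regulator of G-protein signalling, PCNX3 and ZDHHC16, a palmitoyltransferase, rose by 0.95, 0.91, 0.89 and 0.81. Leaving out sinc replicate 1 ended the calls on STX12, MED11 and PCNX3, and leaving out sinc replicate 2 or si replicate 1 ended those on MED11 and PCNX3. None of the 10 increased genes from OGFR to ZDHHC16 had a run longer than 10 bases in common with the SOGA1 stretch, and none held TGAAGTA in its 3' UTR.

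**Figure D2:**
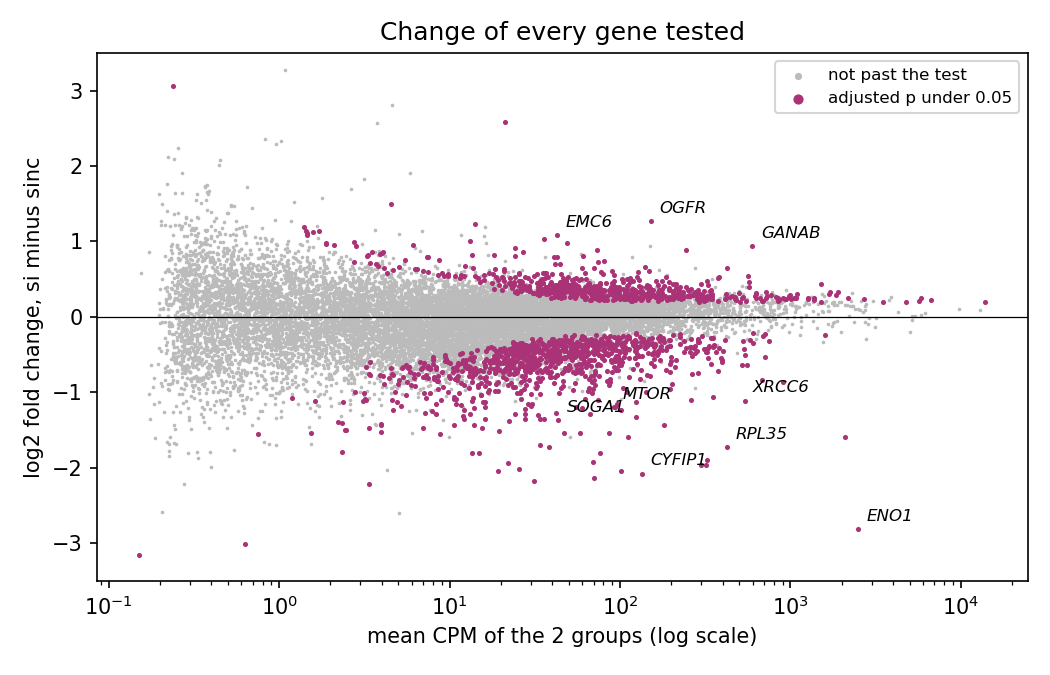
Log2 fold change of each gene tested, si minus sinc (vertical axis), against its mean CPM over the groups (horizontal axis, log scale), with genes at an adjusted p under 0.05 in colour and 8 genes beyond the axis limit of 3.5 not drawn. ENO1 lies at -2.82 among the abundant genes, and at 2-fold or more 122 genes are lower and 15 higher.

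Genes that act in mitosis were lower in si. Of 42 members measured, 13 fell, 0 rose and 29 did not pass; adjusted over the list alone, 20 were lower. By edgeR at an unadjusted p under 0.05, by DESeq2 and by limma-voom 23, 18 and 13 were lower and 0 higher. BUB1, a spindle checkpoint kinase, NUF2, a kinetochore protein, INCENP, the scaffold of the chromosomal passenger complex, and the kinase AURKA had log2 fold changes of -0.56 (SE 0.09), -1.11 (SE 0.18), -0.59 (SE 0.10) and -0.55 (SE 0.10). The list had a median change of -0.31 and was called lower by camera (adjusted p = 1.73e-06). With an estimated correlation the call was lost (adjusted p = 0.22). After correction for length and GC content the median was -0.18 and the call held (adjusted p = 1.02e-06). The number of lower members was 0 without sinc replicate 1 or 3, 1 without si replicate 1, 4 without sinc replicate 2 and 18 without si replicate 2. At the preset correlation camera still called the list lower in all 6 fits with a library left out (largest adjusted p = 2.65e-05). Its mean change there lay between -0.30 (without sinc replicate 1) and -0.48 (without si replicate 2), so that mainly calls on single genes were lost. All 4 named members lost their calls without sinc replicate 1 or 3, BUB1, NUF2 and AURKA also without si replicate 1, and AURKA also without sinc replicate 2.

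DNA damage repair genes were also lower, with 6 of 37 measured members down, 0 up and 31 not past the test (7 lower adjusted over the list alone). By edgeR at an unadjusted p under 0.05, by DESeq2 and by limma-voom 15, 12 and 7 were lower and 0 higher. XRCC6, the Ku70 subunit of the end-joining machinery, had a log2 fold change of -1.11 (SE 0.06) and was abundant, at 739 ± 31.7 CPM in sinc and 342 ± 20.01 CPM in si (SD, n = 3 each). The DNA-dependent protein kinase gene PRKDC and PARP1 stood at -0.95 (SE 0.17) and -0.43 (SE 0.08). XRCC6 shares an 11-base run with the SOGA1 stretch. Camera called the list lower (adjusted p = 0.0071), and with an estimated correlation it did not (adjusted p = 0.75). The members have a median transcript length of 4180 bases, and the call ended after correction for length and GC content (adjusted p = 0.20; median -0.34 before and -0.0033 after). The number of lower members was 2 without sinc replicate 1, sinc replicate 3 or si replicate 1, 3 without sinc replicate 2 and 13 without si replicate 2. At the preset correlation camera still called the list lower in all 6 fits with a library left out, narrowly without si replicate 1 (adjusted p = 0.0499). PRKDC and PARP1 lost their calls without sinc replicate 1, sinc replicate 3 or si replicate 1, and PARP1 also without sinc replicate 2.

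Chaperones of the endoplasmic reticulum and genes of the unfolded protein response fell in 8 of 28 measured members and rose in 1, with 19 not past the test (12 lower and 1 higher adjusted over the list alone). The lectin chaperone CANX fell by 0.84 (SE 0.06), from 875 ± 28.7 to 490 ± 27.9 CPM (SD, n = 3 each). ATF6, a sensor of the response, fell by 0.66 (SE 0.07), the chaperone HSP90B1 fell by 0.62 (SE 0.07) and HYOU1 fell by 0.41 (SE 0.06), and all 4 passed with each library left out. HYOU1 shares a 12-base run with the SOGA1 stretch. CRELD2, which is induced under endoplasmic reticulum stress, was the member that rose (0.41, SE 0.08). It was named after its value was seen, and no member rose without sinc replicate 1, 2 or 3 or si replicate 1. Camera called the list lower (adjusted p = 0.0077; adjusted p = 0.71 with an estimated correlation). The call was lost without si replicate 2 (adjusted p = 0.10). The number of lower members was 4 without sinc replicate 1 and 5 without sinc replicate 3.

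Cytosolic ribosomal protein genes were higher in si by a small amount. Of 68 members measured, 24 rose, 1 fell and 43 did not pass (54 higher and 2 lower adjusted over the list alone), and the median change was 0.21. RPS28, RPL30 and RPL11 rose by 0.29 (SE 0.05), 0.28 (SE 0.05) and 0.25 (SE 0.05). RPL35 went the other way, from 656 ± 45.9 CPM in sinc to 198 ± 42.5 CPM in si (SD, n = 3 each; log2 fold change -1.73, SE 0.15, adjusted p = 0.0013). Its transcript shares 18 bases in a row with the SOGA1 stretch. Camera called the list higher (adjusted p = 8.17e-11), and with an estimated correlation the call was lost (adjusted p = 0.84). Ribosomal protein genes took 9.07 ± 0.107% of counts in si and 8.22 ± 0.222% in sinc (SD, n = 3 each; exact permutation p = 0.1, two-sided). The transcripts are short, with a median of 899 bases, and after correction for length and GC content the median change was 0.08 and the call held (adjusted p = 0.018). Without sinc replicate 1, sinc replicate 3 or si replicate 1 no member passed as higher (0 of 68), without sinc replicate 2 it was 1, and without si replicate 2 it was 16. At the preset correlation camera still called the list higher in all 6 fits with a library left out (largest adjusted p = 4.74e-08). Its mean change there lay between 0.14 (without sinc replicate 3) and 0.20 (without sinc replicate 2). RPS28, RPL30 and RPL11 each lost the call without sinc replicate 1, 2 or 3 or si replicate 1, and RPL35 kept it with each library left out.

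Nuclear-encoded genes of oxidative phosphorylation were higher as well: 15 of 42 measured members rose, 1 fell and 26 did not pass (26 higher and 1 lower adjusted over the list alone), with a median change of 0.20. CYC1 of complex III rose by 0.31 (SE 0.06) and NDUFA8 of complex I by 0.43 (SE 0.08). The complex I subunit NDUFS8 fell by 1.09 on the log2 scale (SE 0.07), from 84.8 ± 2.21 to 39.8 ± 2.86 CPM (SD, n = 3 each), and its transcript shares a 12-base run with the SOGA1 stretch. Camera called the list higher (adjusted p = 1.73e-06; adjusted p = 0.75 with an estimated correlation). After correction for length and GC content the median was 0.13 and the call held (adjusted p = 0.0053). The number of members that rose was 1 without sinc replicate 1, sinc replicate 3 or si replicate 1, 3 without sinc replicate 2 and 9 without si replicate 2. At the preset correlation camera still called the list higher in all 6 fits with a library left out (largest adjusted p = 3.87e-05). Its mean change there lay between 0.15 (without sinc replicate 1) and 0.19 (without sinc replicate 2). CYC1 and NDUFA8 lost their calls without sinc replicate 1, sinc replicate 3 or si replicate 1, and NDUFA8 also without sinc replicate 2. Of 13 genes encoded in the mitochondrial genome 0 passed by edgeR, and 0 also at an unadjusted p under 0.05, by DESeq2 and by limma-voom; MT-CO1 stood at 5261 ± 919 CPM in sinc and 5111 ± 2438 CPM in si (SD, n = 3 each). Their share of counts was 1.26% in si replicate 3 and between 2.21% and 3.31% in the other 5 libraries.

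In the list of microtubule and Golgi organisation, 6 of 35 measured members fell and 1 rose (6 and 1 adjusted over the list alone), without a call by camera (adjusted p = 0.26) and with one as lower by limma's fry test (adjusted p = 0.027). By camera with an estimated correlation it was not called (adjusted p = 0.76). The dynein heavy chain gene DYNC1H1 fell by 0.64 (SE 0.07), from 631 ± 13.5 to 404 ± 30.5 CPM (SD, n = 3 each). The microtubule plus-end protein gene CLASP1 and the centrosomal gene CDK5RAP2 stood at -0.64 (SE 0.08) and -0.78 (SE 0.11), and the tubulin gene TUBA1C at 0.30 (SE 0.05). The number of lower members was 2 without sinc replicate 1, 3 without sinc replicate 3 or si replicate 1 and 11 without si replicate 2. CDK5RAP2 lost its call without sinc replicate 1, and TUBA1C without sinc replicate 1, sinc replicate 3 or si replicate 1. DYNC1H1 shares an 11-base run with the SOGA1 stretch and CLASP1 holds TGAAGTA in its 3' UTR.

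In hypoxia and glycolysis, 7 of 35 measured members rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.26). Beside the fall of ENO1, the lactate transporter SLC16A3 and the glycolytic enzyme PGAM1 rose by 0.37 (SE 0.06) and 0.27 (SE 0.05). The collagen prolyl hydroxylase gene P4HA1 and the lysyl oxidase gene LOX stood at -0.60 (SE 0.12) and -0.32 (SE 0.08). After the correction for length and GC content LOX was at 0.074 and no longer passed. Without sinc replicate 1 or si replicate 1 the number that rose was 0, without sinc replicate 2 or 3 it was 1, and in each of these 4 fits 1 member, ENO1, fell.

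Apoptosis regulators rose in 7 of 32 measured members and fell in 2 (10 and 3 adjusted over the list alone; camera adjusted p = 0.088). The list was called higher by limma's fry test (adjusted p = 0.015), by camera on the 12829 genes with a coding transcript (adjusted p = 0.046) and after correction for length and GC content (adjusted p = 0.020), but not with an estimated correlation (adjusted p = 0.71). The genes BBC3, BAX and FADD, which promote cell death, rose by 0.59 (SE 0.09), 0.27 (SE 0.05) and 0.43 (SE 0.09). All of them lost their calls without sinc replicate 1, sinc replicate 3 or si replicate 1, and BAX and FADD also without sinc replicate 2. BBC3 and BAX are also members of the list of p53 targets. The members that fell, named after their values were seen, were the apoptosome gene APAF1 (-0.88, SE 0.20) and the survival gene BCL2 (-0.67, SE 0.17). The number that rose was 1 without sinc replicate 1, sinc replicate 3 or si replicate 1 and 2 without sinc replicate 2, and in these fits 0 fell.

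Of p53 targets, 7 of 30 measured members rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.24). Without genes that share sequence with the SOGA1 stretch, a choice made after the data were seen, camera called the remaining 22 members higher (adjusted p = 0.037; mean change 0.15, against 0.057 for all 30). That stretch was picked for the low values of its carriers in these data, so the rise and the call are partly built in. With an estimated correlation the whole list was not called (adjusted p = 0.85). CCNG1 had the largest change of these, from 128 ± 7.48 to 44.2 ± 3.55 CPM (SD, n = 3 each; log2 fold change -1.54, SE 0.08), and its 3' UTR holds a 13-base run of the SOGA1 stretch that ends in TGAAGTA. TRIAP1 and FBXO22 rose by 0.50 (SE 0.08) and 0.39 (SE 0.06), and TP53INP1, named after its value was seen, stood at -0.73 (SE 0.13). The number that rose was 0 without sinc replicate 1, 1 without si replicate 1 and 2 without sinc replicate 2 or 3, and in each of these fits 1 fell.

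Of 40 interferon-stimulated genes 0 passed by edgeR, and 0 also at an unadjusted p under 0.05, by DESeq2 and by limma-voom. The abundant IFITM3 stood at 483 ± 123 CPM in sinc and 666 ± 170 CPM in si (SD, n = 3 each). Its values were 549, 558 and 342 CPM in sinc replicates 1, 2 and 3, and 761, 767 and 471 CPM in si replicates 1, 2 and 3. Replicate 3 was thus the lowest in both groups, and each si value lay above the sinc value of the same number. These tests do not use the numbers. With the replicate number as a block camera did not call the list either (adjusted p = 0.092, against 0.70 in the main fit). Among 8 endothelial and 6 fibroblast markers measured 1 each passed, TIE1 (0.24, SE 0.06) and COL1A1 (0.34, SE 0.06). Both calls ended without sinc replicate 1, 2 or 3 or si replicate 1, and that of TIE1 also without si replicate 3. The fibroblast list had a median of -0.016, below 0, and its camera direction was up (adjusted p = 0.67).

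**Figure D3:**
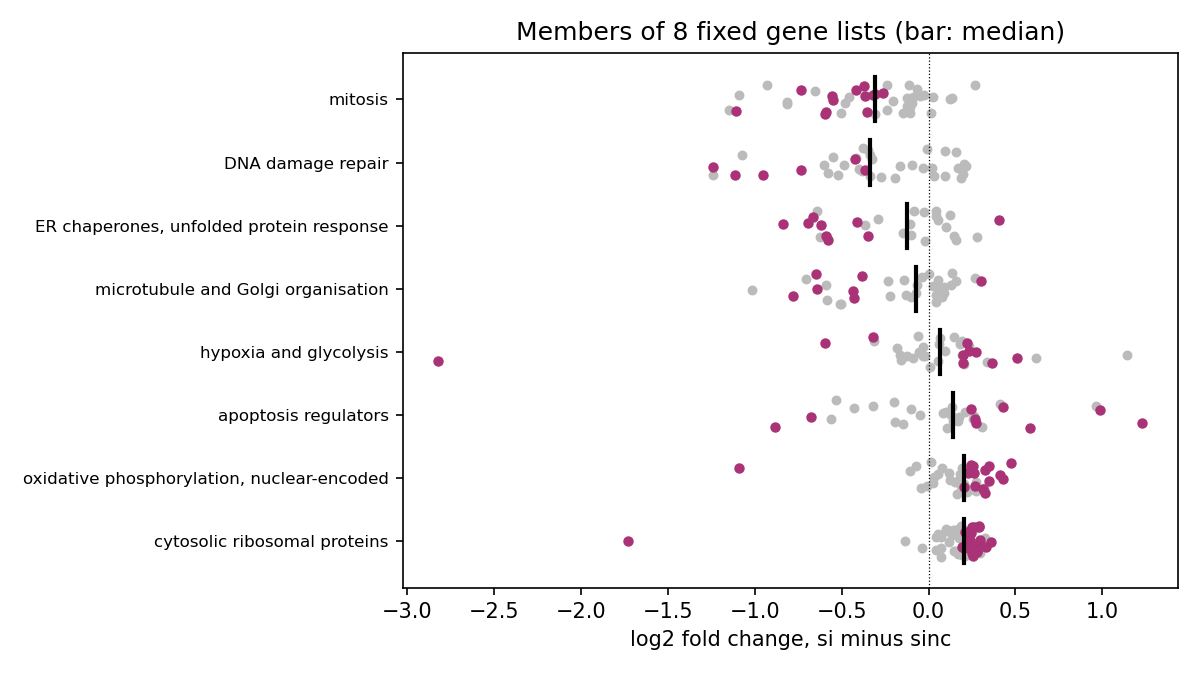
Log2 fold change, si minus sinc (horizontal axis), of the measured members of 8 gene lists, with 1 point per gene, coloured where the adjusted p was under 0.05, and a bar at each list's median. Mitosis genes have a median of -0.31 and ribosomal protein genes one of 0.21, with RPL35 at -1.73 apart from the others.

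Across genes, the change between the groups went with transcript length and GC content. Over 12829 genes with a coding transcript in the reference annotation, Spearman's rho with the log2 fold change was -0.47 for length and 0.49 for GC content, where genes are not independent replicates. The deviation of each library from the mean of all 6 had a rho with length of 0.45, 0.26 and 0.29 in sinc replicates 1, 2 and 3, and of -0.43, -0.09 and -0.33 in si replicates 1, 2 and 3.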

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

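The length and GC correction, the fit on the same genes without it and the counts without sequence-sharing genes were chosen after the results were seen. SOGA1 stayed lower and past the threshold under all 16 alternatives, from -1.47 without si replicate 2 to -1.13 after the length and GC correction. Of the 1579 changed genes, 189 passed in all 6 fits with a library left out. The count was 2806 by DESeq2 (1158 higher, 1648 lower), 844 without a filter, 585 after the length and GC correction (242 higher, 343 lower), 1162 without genes that share sequence with SOGA1 (605 higher, 557 lower), and between 203 (without sinc replicate 1) and 2563 (without si replicate 2) with a library left out. At 2-fold it was 79 after that correction, 61 without genes that share sequence with SOGA1 (15 higher, 46 lower), and between 71 and 613 with a library left out, at the same libraries. The other scalings, limma-voom and the minimum count of 50 moved neither count by over 1.5 times, and the scalings moved the median change of all genes to between -0.020 and 0.029. The number of lists called was 0 with an estimated correlation and between 4 (without si replicate 2) and 12 (without si replicate 3) with a library left out, against 5. It was 7 by fry, which added apoptosis regulators and microtubule and Golgi organisation, and 6 after the length and GC correction, which dropped DNA damage repair and added apoptosis regulators and ribosome biogenesis and MYC targets. Without si replicate 3 the calls included interferon-stimulated genes and mitochondrially encoded transcripts, both higher, at the preset correlation. Without genes that share sequence with SOGA1 it was 6, with p53 targets added as higher (adjusted p = 0.037). The shared sequences were picked for the low values of their carriers in these data, so leaving those genes out removes mostly decreases as a result. Antigen presentation, not called in the main fit (adjusted p = 0.069), was called higher under 6 alternatives, among them the minimum count of 50 (adjusted p = 0.043), and not after the length and GC correction (adjusted p = 0.38) or with an estimated correlation (adjusted p = 0.89). Adding the replicate number as a block gave 438 genes, 99 of them at 2-fold, and 6 lists. Over all genes same-numbered libraries did not deviate together (correlations -0.18, -0.03 and 0.15), and not every library correlated best with its own number. The numbers were therefore not taken as pairs, but a factor shared by a number in part of the genes is not excluded. Both replicates 3 lay highest on the second principal component (27.9 in sinc and 23.7 in si, the others at most 4.0). Both also had the lowest mitochondrial share of counts in their group (2.21% and 1.26%). Named genes that changed sign did not pass there: LOX at 0.074, IDS at 0.12 and HIST1H2BK at -0.20 after the length and GC correction, MT-CO1 at 0.074 without sinc replicate 1 and 0.30 without si replicate 3 (lowest -0.29 without si replicate 2), and MT-ND4 at 0.022 without si replicate 3 (lowest -0.56 without si replicate 2). Fits with fewer libraries have fewer degrees of freedom; the cause of the other changes was not tested. Of 121 named genes past the threshold, 38 kept their call with each library left out.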

Other observations

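The search for shared sequence, the length and GC correction, and the tests of shared sequence, of a consequence of lower SOGA1 and of the list calls against length and GC content were chosen after the results were seen. In cholesterol biosynthesis, 3 of 25 measured members fell and 1 rose (3 and 3 adjusted over the list alone; camera adjusted p = 0.97), with a median of 0.061 and a mean of -0.038. MSMO1 fell by 0.55 (SE 0.08) and SQLE fell by 0.52 (SE 0.07), while EBP rose by 0.30 (SE 0.06). MSMO1 and SQLE lost their calls without sinc replicate 1, which left 1 member that fell, and EBP lost its call without sinc replicate 1, 2 or 3 or si replicate 1.

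Among ribosome biogenesis and MYC targets 7 of 33 measured members fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.18). After the length and GC correction the list was called lower (adjusted p = 0.018), as it was without a filter (adjusted p = 0.036) and without si replicate 3 (adjusted p = 0.00074). With an estimated correlation it was not called (adjusted p = 0.89). The largest change was that of MYBBP1A, from 167 ± 2.99 to 55.1 ± 6.24 CPM (SD, n = 3 each), which passed with each library left out and whose transcript shares an 11-base run with the SOGA1 stretch. The number that fell was 2 without sinc replicate 1, 3 without sinc replicate 2, 1 without sinc replicate 3 or si replicate 1, and 14 without si replicate 3. In epithelial junctions and keratins 3 of 29 fell and 0 rose by edgeR (3 and 1 adjusted over the list alone; 6 and 5 at an unadjusted p under 0.05, 4 and 1 by DESeq2, 3 and 1 by limma-voom; camera adjusted p = 0.83), with a median of 0.052 and a mean of -0.043. The desmosome genes DSP and DSG2 stood at -1.54 (SE 0.29) and -0.54 (SE 0.11) and the tight junction gene TJP1 at -0.71 (SE 0.14), and all 3 calls ended without sinc replicate 1, 2 or 3 or si replicate 1. DSP shares a 14-base run with the SOGA1 stretch, and TJP1 holds TGAAGTA in its 3' UTR.

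Genes at least 2-fold lower outnumbered those at least 2-fold higher by 122 to 15. Against the trend in length and GC content as the whole cause, 69 genes were still at least 2-fold lower and 10 higher after its correction, although 121 were lower on the same genes without it, so that 69 is only a little over the bound of 0.5 times set for this test and the trend may account for a large part. A candidate explanation for another part is that the reagent used on the si cells acted on transcripts that share its sequence. GGAGCTGCTGAA, found in SOGA1 and 57 other genes, had the lowest z of 2160 12-base sequences of SOGA1 (z = -15.9). Its mean residual was -0.73 on the log2 scale against genes without it, SOGA1 left out. On a random part of the genes the lowest was this sequence, and on the rest it was GAGCTGCTGAAG, which overlaps it in SOGA1. On the genes not used to pick it, each was the second lowest (z = -8.33 and -12.4, of 2322 and 2300 sequences) and lower than its testable single-base variants (lowest z = -4.07 and -3.23). TGAAGTA, which starts 8 bases after it in SOGA1, was the lowest 7-base sequence in 3' UTRs (z = -9.18, 1465 genes) and again in each random part of the genes when picked on the other (z = -5.90 and -7.11). Of 112 genes at least 2-fold lower with a coding transcript, SOGA1 aside, 67.0% held TGAAGTA in the 3' UTR or a run of at least 11 bases of the stretch, against 18.4% of genes not past the test and 0 of 11 at least 2-fold higher, and since the stretch was set on the same genes the first share may be too high. Of all 918 genes lower at any size, 41.0% held either and 59.0% neither. Among all genes tested with a coding transcript, SOGA1 aside, 19.5% held either, and these shares were not matched for transcript length. Of the 112 genes at least 2-fold lower, 33.04% carried neither. The sequence of the reagent is not given in the sources used here. With 1 si group a consequence of lower SOGA1 and other effects of the reagent cannot be told apart for these genes. Nor can the cause be settled for any single gene that carries a shared sequence.

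Further values bear on that search. The highest 12-base sequence of SOGA1, CACTTTGGGAGG, had a z of 8.48 over 1053 genes, a size near that of TGAAGTA with the opposite sign. In coding sequence the lowest 7-base sequence was AAAGAGA (z = -7.47), which is not part of the stretch. SOGA1's transcript holds 46.3% of all 7-base sequences. Of 100 other transcripts 0 had a 12-base sequence as low as that of SOGA1 (lowest z = -7.87). The single gene with 1 mismatch over the 21 bases, WWC1, had a log2 fold change of -1.13. Of the 3 genes with 2 mismatches, RPL35 stood at -1.73, while XDH and MAFF stood at 0.14 and 0.30 and did not pass; WWC1, XDH and MAFF are named after their values were seen. The 31 genes with 3 mismatches had a median of -0.35 and the 127 with 4 one of -0.09, and 19.4% and 8.66% of them were at least 2-fold lower. Of 728 genes with a longest run of 11 bases 1.37% were at least 2-fold lower, against 10.1% of 109 with 13 and 3 of 5 with 16. By copies of TGAAGTA in the 3' UTR the median residual was -0.057 with 1 copy (1191 genes) and -0.077 with 2 (220 genes). It was 0.064 with 3 (41 genes) and 0.11 with 4 (9 genes), against 0.025 with 0, so that it did not fall further beyond 2 copies. The uncorrected median changes were -0.29, -0.38, -0.31 and -0.40 with 1, 2, 3 and 4 copies, against 0.016 with 0. The residual is corrected for 3' UTR length, and a longer 3' UTR can hold more copies. These medians therefore cannot decide for or against this sequence as the cause in those genes. The share at least 2-fold lower was 2.10% with 1 copy, 2.73% with 2, 4.88% with 3 and 2 of 9 with 4, against 0.669% with 0.

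The 5 list calls may follow transcript length in part. After the length and GC correction 4 of the 5 lists were still called in their direction at the preset correlation. Mean changes shrank, from -0.35 to -0.22 for mitosis and from 0.17 to 0.072 for ribosomal proteins. Without the correction, camera at this setting also called up to 11 lists on splits that mix the groups. The held calls therefore cannot decide whether the trend was their whole cause. The DNA damage repair list lost its call, as its mean moved towards 0, from -0.33 (SD over members 0.41) to -0.11. The correction is fitted to the same libraries with the group difference in them. It would therefore also remove a true fall that goes with length or GC content, so the lost call cannot decide the cause either. The correction also gave a pair of calls that the main fit lacks, apoptosis regulators as higher, which camera called on the same genes without it too, and ribosome biogenesis and MYC targets as lower, each at the preset correlation. Of the 10 ways to split the 6 libraries 3 against 3, 3 gave at least 5 lists, the real split included, and the highest other gave 11, which points to a structure of the libraries besides the group. On the first principal component, with 39% of the variance, si replicate 2 lay at -13.0, among the sinc libraries (-40.6 to -11.0) and away from si replicates 1 and 3 (37.1 and 45.3). Its log2 CPM correlated better with sinc replicates 1 and 2 (0.982 and 0.984) than with si replicates 1 and 3 (0.979 and 0.974), while by chi-square per gene on counts it was nearest to si replicate 1 (20.2) and its SOGA1 level was 27.2 CPM. What sets it apart was not tested. The splits are too few for a share under 0.05. What made the length trend differ between the groups was not tested.

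For gene counts, the real split gave 1579 genes and the highest of the other splits gave 1, and at least 2-fold the values were 137 and 1. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.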
